A study of Mus musculus with 4 samples.

How the data were processed

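The samples were 4 RNA-seq libraries of mouse spleen CD8 T cells: naive and virtual memory cells from untreated mice and from mice given IL-15C. Per the labels' protocols, CD8 cells were enriched with anti-CD8 microbeads and sorted on CD44 and CD49d, poly(A) RNA was made into libraries with a stranded TruSeq kit, and these were read as pairs on a NovaSeqX. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.3b, edgeR and R 4.2.2 with the mm10 build, without the role or order of each. Whether reads were counted by strand, and which annotation version was used, is not given in the sources used here.

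A single table of 15466 genes, keyed by Entrez ID, was used. The read counts per gene were deposited by the authors as whole numbers without normalization, per the file headers. FPKM values, fragments scaled to transcript length and library size, were deposited by the authors, per the file headers. TPM values were deposited by the authors, per the file headers, and the genes in the table fall short of the full TPM total by 0.0397% to 0.166% in the 4 libraries. The deposited normalized columns hold the log2 of 1 + CPM after TMM scaling: recomputed from the counts, they differ from the authors' values by at most 5.0e-09. The authors also deposited a signed fold change for 5 comparisons and a Benjamini-Hochberg adjusted p-value beside each fold, without naming the test, and 4 of these comparisons have 1 library per side. The smallest count in the table is 1, so the table lists genes with a read in each of the 4 libraries. Genes without a read in 1 or more libraries, which include those most restricted to a group, were not analysed here. A further 10 columns of per-sample values were not used. Columns headed ctrl were taken as the untreated groups, which the labels call wild type. No row lacked a gene name. Of the Entrez IDs, 15428 matched the RefSeq annotation of GRCm38.p6, which gave coordinates, and 38 did not. GENCODE M21 on GRCm38 served for exon overlaps and GC content.

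The design written before the data were examined foresaw replicates or their absence. With 1 library per group, no test and no p-value across genes was computed. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) of 1.04 for untreated naive, 1.02 for untreated virtual memory, 0.996 for IL-15C naive and 0.946 for IL-15C virtual memory cells. Log2 ratios used a prior count of 2. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals of the ratio of the 2 counts, without the prior count, and cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was compared if it had at least 20 reads in the 2 libraries together and 1 CPM in the higher one, and was counted as higher or lower if it differed at least 2-fold with the whole interval beyond 2-fold. The median width of the interval was 0.234, 0.238, 0.230 and 0.249 log2 units in the 4 comparisons. For the difference between the 2 IL-15C responses the limits were 4-fold, 20 reads over the 4 libraries and 1 CPM in the highest. Overlaps of gene sets are given beside the number that independent lists would share, from the genes compared in both. The 10 most counted genes took 6.45% to 7.31% of the reads.

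The 27 gene lists were written before the data were examined. They hold 402 entries for 376 distinct genes, of which 328 are in the table. The median log2 ratio of a list was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and counted as outside when beyond the 2.5 or 97.5 percentile. This describes these libraries and is not a test across mice. The lists cover the naive state, virtual memory markers, the sort gate, cytotoxicity, NK receptors, chemokines, integrins, inhibitory receptors, STAT5 targets, interferon-induced genes, replication, mitosis, glycolysis, oxidative phosphorylation, fatty acid oxidation, amino acid uptake, immediate early genes, apoptosis, transcription factors, T cell receptor signalling, sex-linked genes (Xist was not analysed here), and markers of B cells, macrophages and granulocytes, dendritic cells, CD4 cells, NK and gamma-delta cells, and erythroid cells and platelets. Some are shared: Itgax is also an integrin gene, Ccr9 also a naive gene, and Ctla4, Il2ra, Ikzf2, Klrb1c, Tyrobp and Fcer1g also belong to lists of T or NK cell genes.

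Genes were named by a rule fixed before the data were examined. Per comparison these were the 10 with the highest and the 10 with the lowest log2 ratio among those counted and reaching 10 CPM in the higher library, leaving out predicted and clone-named genes, immunoglobulin and T cell receptor segments, ribosomal protein, histone and mitochondrial genes and pseudogenes. For the difference between responses 5 in each direction were taken, and not every gene so chosen is given in the text. Each list adds members with the largest differences, or those with the highest expression where none was counted, and Cd44, Itga4, Ly6a, Ly6c1, Ly6c2, Il2rb, Eomes, Tbx21, Gzmb, Ifng, Klrk1 and Cd8a were always named. Igkc, Ddx3x, Kdm6a, Eif2s3x, Med12l and Gm20716 were chosen after their values were seen, as were further list members given for comparison between libraries. Same-strand exon overlaps make the reads of Rsc1a1 (with Ddi2), Dpm1 (Gm20716), L1cam (Arhgap4), S100a4, Ifng, Ccr9, Carns1, Dlg5, Cd74 and Zbtb20 uncertain, and the same holds for the paralogs Ly6c1 and Ly6c2 and the Klrc family. Opposite-strand overlaps affect Acvrl1, Ago2, Ccna2, Cd22, Cnn3, Eomes, Gprc5b, Grm6, Itga4, Mxd3, Neb, Nusap1, Pkd1, Plek, Slfn5 and Troap if the counting ignored strand.

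The procedure was tested on simulated data with counts drawn at the real depths. With counting error alone, 8-fold changes were recovered in 100.0% of cases in every comparison, and 3-fold changes in 91.7% (virtual memory against naive, untreated, 12167 genes), 89.5% (the same in IL-15C mice, 12136 genes), 98.2% (IL-15C in naive cells, 12136 genes) and 98.4% (IL-15C in virtual memory cells, 12132 genes), with 0 unchanged genes counted. When a coefficient of variation of 0.2 was added per gene and library, 77, 77, 72 and 91 of 12000, 11989, 11996 and 11995 unchanged genes passed the limits in the same 4 comparisons. With this added spread 3-fold changes were recovered in 73.3%, 80.0%, 80.0% and 89.1% of cases, 4-fold changes in 95.6%, 97.8%, 94.4% and 96.9%, and 8-fold changes in 98.7% in the second comparison and 100.0% in the others. For the difference between responses, simulated with counting error alone, 100.0% of 200 genes with an 8-fold difference were recovered among 12240 genes, and 0 unchanged genes passed. These counts were drawn around the mean of each gene over the 4 libraries. Unchanged genes with few reads in only some libraries, and the added spread, were therefore not covered.

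Alternatives were size factors from DESeq2 1.42.0, library totals, no filter, a filter at 5 CPM, prior counts of 0.5 and 10, a 4-fold limit, the deposited FPKM and TPM as log2(value + 1), and lists without genes that another list holds. Removal of a trend with effective transcript length (lowess, fraction 0.3, length from the deposited counts and FPKM) was added after the data had been seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.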

Results

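Gene expression was measured by stranded poly(A) mRNA sequencing in CD8 T cells sorted from the spleens of C57BL/6 mice. The mice were either left untreated with cytokine (wild type, given buffer) or given IL-15C, a complex of the cytokine IL-15 with its receptor subunit IL-15Ra, 4 times a week. From each, CD8 cells were enriched on magnetic beads and sorted by flow cytometry into naive cells, which lack surface CD44 and CD49d, and virtual memory cells, which carry high CD44 without CD49d. Virtual memory cells are memory-type CD8 T cells that arise without known antigen exposure and depend on IL-15. The 4 groups (untreated naive, untreated virtual memory, IL-15C naive and IL-15C virtual memory) had 1 library each. The sample titles give 3 mice per group, and whether these were pooled is not stated. The untreated naive library held 48950547 reads assigned to genes, the untreated virtual memory library 43862816, the IL-15C naive library 45649628 and the IL-15C virtual memory library 45289920, so that 1 read corresponded to 0.0197 to 0.0233 CPM, the count scaled to library size. With 1 library per group no difference had a replicate check, and the 95% intervals given here cover counting error only. The comparisons describe these libraries, and whether other mice would give the same values was not measured. A gene was counted as higher or lower when it differed at least 2-fold and its counting interval lay beyond 2-fold. A list's median log2 ratio was called outside the random range when it lay beyond the central 95% of 10000 random lists matched on expression. Genes without a read in 1 or more of the 4 libraries were not analysed here, which leaves out transcripts restricted to some groups, and some lists were measured in part, such as the NK receptors with 10 of 20 genes. Gene coordinates are on GRCm38, the assembly also called mm10.

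The first comparison asked how virtual memory cells differed from naive cells in untreated mice. Cd44, the gene of the sorted marker (Entrez 12505, chromosome 2, 102811141 to 102901669), stood at 232 CPM in virtual memory and 8.65 CPM in naive cells, a log2 ratio of 4.74 (95% counting interval 4.61 to 4.89). Genes of memory and killer cell type receptors went with it. Il2rb, the beta chain shared by the IL-2 and IL-15 receptors, had a log2 ratio of 2.40 (2.37 to 2.43), the T-box transcription factor gene Tbx21 had a ratio of 4.68, and Eomes, of the same family, was at 219 against 38.5 CPM. The Ly6c2 transcript, which encodes the surface protein Ly6C, was at 827 CPM against 156 CPM (log2 2.40, Entrez 100041546, chromosome 15, 75108161 to 75112066). Its close paralog Ly6c1 had a ratio of 2.43, and reads of the pair could be divided between them by the counting. Ly6a, which encodes Sca-1 (Entrez 110454, chromosome 15, 74994877 to 74998031), was at 25.6 CPM in virtual memory and 20.4 CPM in naive cells, a ratio of 0.33.

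Of 12259 genes compared in untreated mice, 590 were higher and 136 lower in virtual memory cells. Among the largest ratios of genes of at least 10 CPM were those of Cd163l1 (log2 9.11), Cd22 (8.41, counting interval 7.66 to 11.49, with 3 reads in naive cells), Plek (8.39), Ccr2 (8.13), Klrk1 (7.42), Klrc1 (7.09), Ccl5 (6.88), Dmrta1 (6.57) and S100a6 (6.55). Klrk1 encodes the activating receptor NKG2D (Entrez 27007, chromosome 6, 129610323 to 129623903), Ccr2 a receptor for inflammatory chemokines and Cd22 a sialic acid-binding receptor best known from B cells (Entrez 12483, chromosome 7, 30865404 to 30880342). At the lower end stood Ccr9, a gut-homing chemokine receptor (log2 −4.06, 235 against 14.1 CPM, Entrez 12769, chromosome 9, 123767211 to 123783457), Igfbp4 (−3.21), Itgae, which encodes the integrin CD103 (−3.05), Acvrl1 (−2.89), Ifngr2 (−2.84), Ntrk3 (−2.82), Grm6 (−2.56), Slc6a19 (−2.42), Lrrc75b (−2.38) and Nfam1 (−2.28).

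Among the gene lists, 12 of 15 virtual memory markers were higher and 0 lower, with a median log2 ratio of 2.43. Those not counted were Ly6a, Bcl2 (0.49) and Nkg7 (0.69). Of 10 NK receptor and adaptor genes 7 were higher, with a median of 4.31, and of 15 cytotoxic genes 6 were higher (median 0.81), including Ifng, which encodes interferon gamma (5.15), Gzmm (5.06), Gzma (3.86) and Gzmb (2.98). Among 16 chemokine and trafficking genes 9 were higher and only Ccr9 lower (median 2.97), with Cx3cr1 at 5.18 and Cxcr3 at 4.24. The effector and memory transcription factors had 11 of 16 higher (median 1.85), among them Zbtb32 (5.47) and Bhlhe40 (4.01). Inhibitory receptor genes had 6 of 13 higher (median 1.09), led by Lag3 (3.98) and Entpd1 (2.90). Integrin and adhesion genes split into 4 higher, with Itgax at 5.76 and Itgb1 at 2.51, and 1 lower, Itgae (median of 14 genes 0.23). Apoptosis regulators had 5 of 15 higher (median 0.49), such as Bbc3 (1.84) and Bcl2l1 (1.58), and STAT5 target genes 4 of 16 (median 0.47), with Il2ra at 1.84.

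Cell-cycle genes were already higher in untreated virtual memory cells. All 20 mitosis genes were higher (median 3.27), Mki67 standing at 117 against 8.22 CPM and Ccna2, cyclin A2, at 23.8 against 1.12 CPM. Of 20 DNA replication genes 11 were higher (median 1.34), with Tk1 at 3.43 and Rrm2 at 3.34. Glycolysis genes had 1 of 17 higher, Hk2 (1.55), and a median of 0.34 above the random range. Immediate early genes had 1 of 16 higher, Fosb (1.38), and a median of 0.24, also above it. Oxidative phosphorylation genes had 0 of 21 on either side and a median of 0.11.

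Below the random range lay the naive and quiescence genes (median −0.39, 2 of 18 lower, Ccr9 and Igfbp4), the interferon-induced genes (median −0.15, 1 of 24 lower, Iigp1 at −1.28) and the 4 sort gate genes (median −0.29, though 1 was higher, Cd44, and 0 lower). Within the last list Itga4, which encodes CD49d, was at 351 CPM in virtual memory and 614 CPM in naive cells (log2 −0.81), although both populations were sorted as lacking the surface protein, and Cd8a had a ratio of −0.26. The 15 T cell receptor signalling genes had 0 members on either side (median 0.00), with Cd3e at 539 and 538 CPM. Medians within the random range were found for fatty acid oxidation (0.10, 0 of 17 on either side), amino acid and iron uptake (0.09, Slc43a1 higher at 2.20 among 9 genes) and 4 Y-linked genes (−0.07, 0 on either side).

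Transcripts typical of other blood cells were higher in the untreated virtual memory library than in the naive one, beside the memory genes above. Of 6 B cell genes 4 were higher, including Cd79a (15.8 against 0.177 CPM) and Ighd (2.11), with a median of 4.14, and Igkc, an immunoglobulin light chain gene chosen after its values were seen, had a ratio of 5.58. Among 7 dendritic cell genes, whose median was 5.14, 5 were higher, with the class II genes H2-Aa at 5.49, H2-Ab1 at 5.39 and Cd74 (106 against 2.97 CPM), and 1 lower, Ccr9, which the naive list also holds. Macrophage and granulocyte genes had 3 of 5 higher (median 2.67; Csf1r 4.80), CD4 and regulatory T cell genes 4 of 6 (median 1.89; Zbtb7b 5.77, Ctla4 2.46), NK and gamma-delta T cell genes 5 of 6 (median 3.90; Tcrg-C2 4.70, Klrb1c 4.54) and erythroid and platelet genes 4 of 5 (median 2.33; Hbb-bs 2.34). With a filter at 5 CPM the medians of the oxidative phosphorylation, macrophage and CD4 lists lay within the random range, though none of the 3 was smaller (0.11, 4.601 and 2.46), and the number of genes differing in either direction was 467 in place of 726. The CD4 list also lay within it without the genes that another list holds, and the oxidative phosphorylation list after removal of a trend with transcript length, while the NK receptor median was 2.80 with the filter and 2.58 without shared genes, and the NK and gamma-delta median 4.54 and 2.45.

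**Figure D1:**
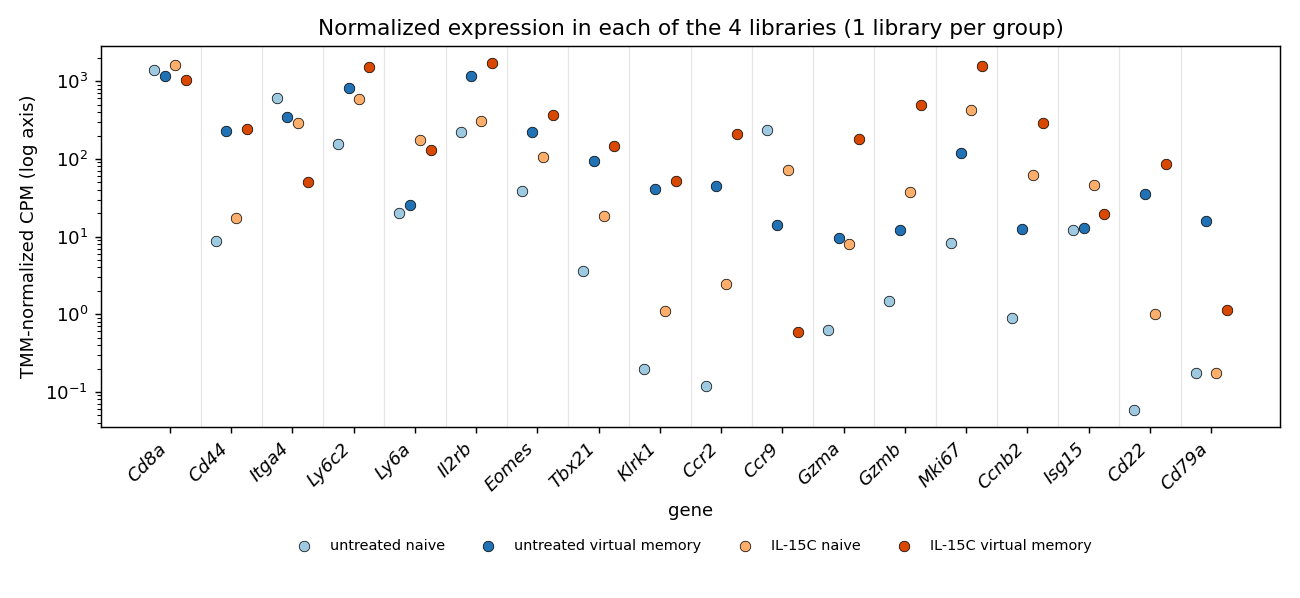
Expression of 18 genes in the 4 libraries, in CPM on a log axis, with 1 point per library. Gzmb ran from 1.49 CPM in untreated naive to 495 CPM in IL-15C virtual memory cells, while Cd8a stayed between 1049.9 and 1603 CPM.

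The same contrast in IL-15C mice asked whether the subsets remained distinct under the cytokine. Cd44 had a log2 ratio of 3.82 (243 against 17.2 CPM) and Il2rb of 2.46, but several markers of the virtual memory state were closer together than in untreated mice: Ly6c2 had a ratio of 1.39, Tbx21 of 2.97 and Klrk1 of 5.51. Ly6a was slightly lower in virtual memory than in naive cells (log2 −0.43, 129 against 174 CPM). Itga4 was at 50.9 CPM against 289.6 CPM in naive cells (log2 −2.51).

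Of 12206 genes compared in IL-15C mice, 796 were higher and 721 lower in virtual memory cells. The largest ratios among the genes ranked, of at least 10 CPM in the higher library, were those of Lrrk1 (log2 6.83), Cd163l1 (6.57), Ccr2 (6.38), Cd22 (6.33), Klrc1 (6.31), Dlg5 (6.30), Fasl, the death ligand of cytotoxic cells (5.83), Itgax (5.75), S100a4 (5.72) and Osbpl3 (5.70). Exons of Dlg5 and S100a4 overlap a predicted gene on the same strand. The lowest ratios among the genes ranked were those of Ccr9 (−6.84), Itgae (−5.50), Mtss1 (−5.35), Igfbp4 (−5.34), Xkrx (−5.22), Gpr34 (−4.98), Cnn3 (−4.88), Ifngr2, a chain of the interferon gamma receptor (−4.76), Gprc5b (−4.70) and the retinoic acid receptor gene Rarg (−4.16).

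Again 12 of 15 virtual memory markers were higher (median 2.27), 8 of 10 NK receptor genes (median 3.93), 8 of 15 cytotoxic genes (median 2.30-fold; log2 Gzmm 5.35, Gzma 4.48, Gzmb 3.71, Ifng 3.41) and 10 of 16 chemokine and trafficking genes, with Ccr9 and Ccr7 lower (median 1.81). Integrin genes had 7 of 14 higher, such as Itga2 (3.03) and Itgam (1.74), and Itgae lower (median 0.73). Transcription factors had 7 of 15 higher, led by Bhlhe40 (4.78), and Rora lower at −1.58 (median 0.89). The naive and quiescence genes lay further below than in untreated mice, with 8 of 18 lower and a median of −0.98. Examples are Sox4 (−3.32), Tdrp (−1.97) and Lef1 (−1.30).

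Interferon-induced genes were lower in virtual memory cells of IL-15C mice in 13 of 24 cases (median −1.08), among them Iigp1 (−3.54), Ifi44 (−3.33) and Ifit1 (−2.66). Immediate early genes were lower in 5 of 16 (median −0.89), with Jun at −1.80 and Nfkbia at −1.54. Mitosis genes were higher in 18 of 20 (median 1.88; Ccnb1 3.07) and replication genes in 8 of 20 (median 0.97; Mcm2 1.46). Glycolysis genes had 5 of 17 higher (median 0.78; Pgam1 1.55, Gapdh 1.21), while oxidative phosphorylation had 0 of 21 on either side with a median of 0.46 above the random range.

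The sort gate genes had a median of −0.56 (1 of 4 higher, Cd44, and 1 lower, Itga4) and the Y-linked genes of −0.88 (1 of 4 lower, Eif2s3y at −1.08), both below the random range. Within it lay the STAT5 targets (0.17, with 7 higher and 3 lower of 17), inhibitory receptors (0.18, 5 of 13 higher), apoptosis regulators (0.06, 3 higher and 1 lower of 15), fatty acid oxidation (0.16, Acadm lower at −1.14 among 17), amino acid uptake (0.10, Slc7a5 higher at 1.19 among 9) and T cell receptor signalling (0.02, 0 of 15). Markers of other cells were again higher: B cell genes in 3 of 6 (median 1.58; Cd22 6.33), dendritic in 4 of 6 with Ccr9 lower (median 2.29), macrophage in 2 of 3 (median 2.27; Cd68 2.90) and NK or gamma-delta genes in 4 of 6 (median 2.67; Klrb1c 5.24). The CD4 list (median 0.70, 2 of 5 higher, Zbtb7b and Il2ra) and the single erythroid and platelet gene with enough reads, Itga2b (−0.87), lay within the range. With the 5 CPM filter the B cell (0.13), macrophage (2.90, not smaller) and NK or gamma-delta (1.43) medians lay within the range, the last also without genes held by another list (1.09), while the inhibitory (1.30) and CD4 (2.24) medians lay above it, the former also without shared genes (0.73). The filter and the removal of shared genes further gave NK receptor medians of 4.88 and 3.02, the filter a dendritic median of 3.00, and the removal chemokine and CD4 medians of 2.41 and 1.84.

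**Figure D2:**
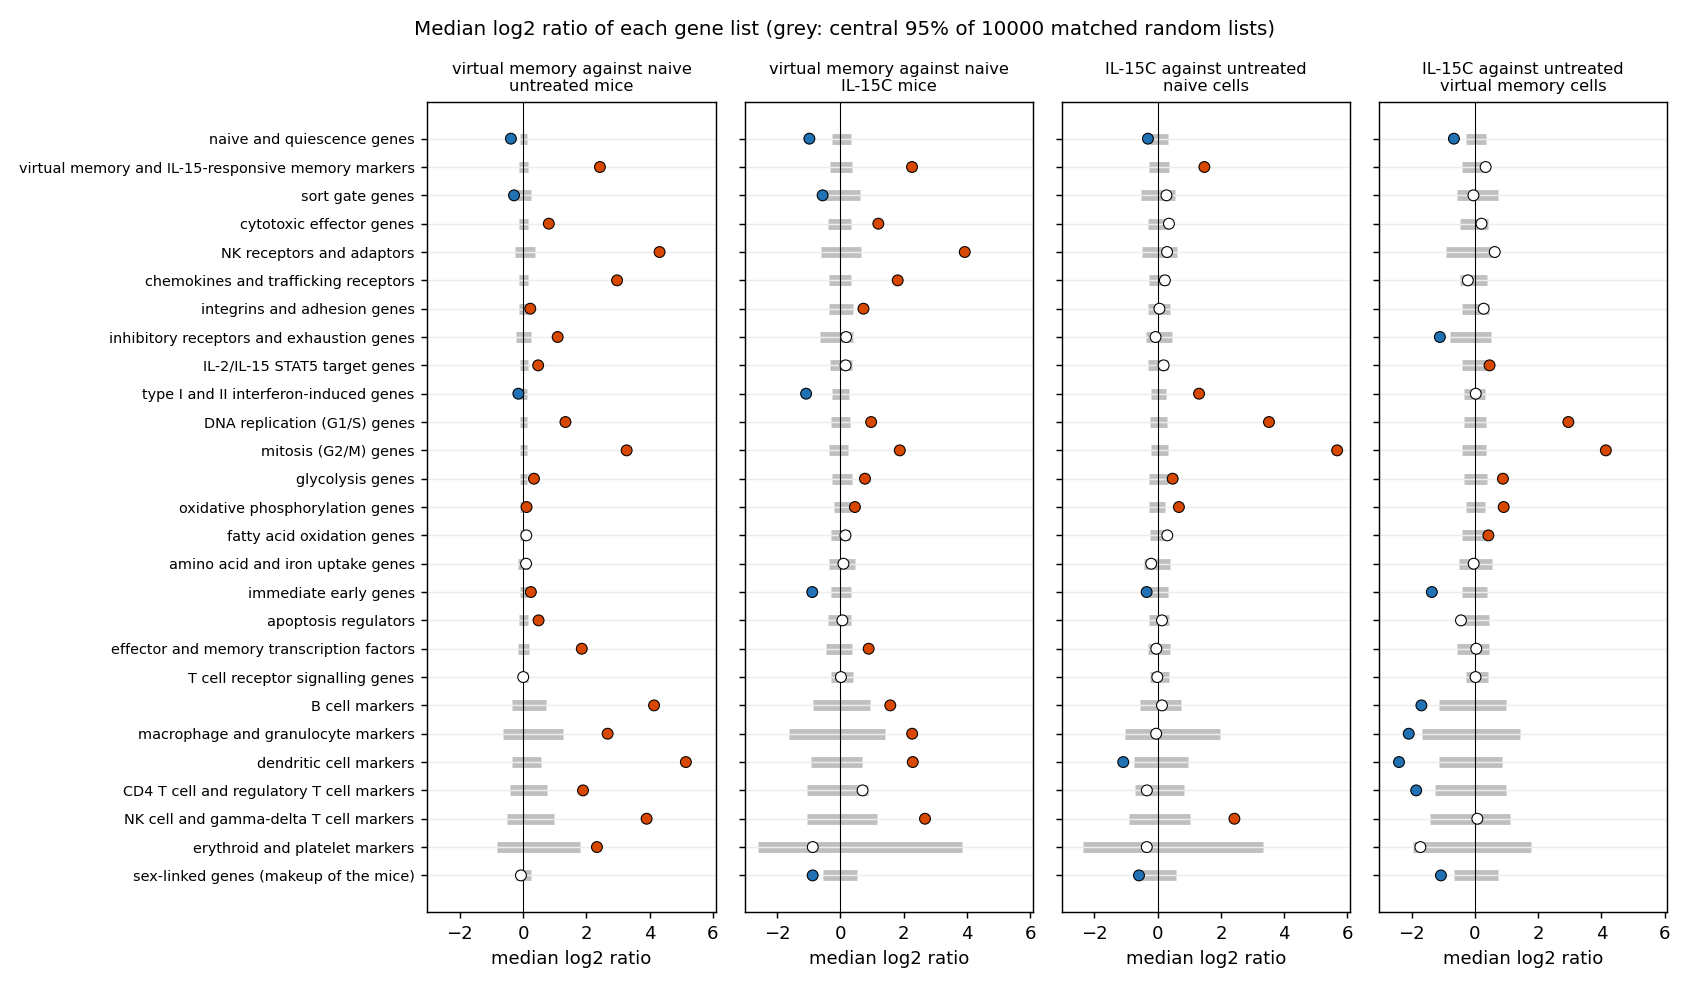
Median log2 ratio of each of the 27 gene lists in the 4 comparisons (dots), with the central 95% of 10000 matched random lists as grey bars. Orange dots lie above the random range, blue dots below it and white dots within it; the mitosis list is above it in all 4 comparisons, from 1.88 to 5.67.

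IL-15C and untreated naive cells were compared to ask what the cytokine complex did in the CD44-negative population. Among the genes ranked, of at least 10 CPM in the higher library, the largest differences were in cell-cycle genes: Pbk had a log2 ratio of 7.31 (95% counting interval 6.63 to 9.21), Kif15, a mitotic kinesin, of 6.81 (6.44 to 7.39), and Ccna2 of 6.78 (128 against 1.12 CPM, Entrez 12428, chromosome 3, 36564865 to 36573038). Gzmb, which encodes the cytotoxic protease granzyme B (Entrez 14939, chromosome 14, 56258836 to 56262334), was at 37.9 against 1.49 CPM (log2 4.62, 4.33 to 5.01). Ly6a was at 174 against 20.4 CPM (log2 3.09, 3.00 to 3.19), and Ly6c2 at 585 against 156 CPM (1.91). Interferon-induced genes were higher as a group, and Cd44 had a ratio of 0.98.

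Of 12174 genes compared in naive cells, 603 were higher and 242 lower with IL-15C. After Pbk, Kif15 and Ccna2 the largest ratios among the genes ranked, of at least 10 CPM in the higher library, were those of Nusap1 (6.74), Mxd3 (6.68), Bub1 (6.67), Esco2 (6.50), Pimreg (6.46), Shcbp1 (6.46) and Ska1 (6.45). Lowest among the genes ranked were the transcriptional repressor gene Zbtb20 (−2.84), Ppm1l (−2.64), Ttc28 (−2.07), Ahnak (−1.89), Carns1 (−1.83), Ago2 (−1.83), Maml3 (−1.75), Nrp2 (−1.71), Ccr9 (−1.71) and Pkd1 (−1.67). Ccna2, Nusap1, Mxd3, Ago2 and Pkd1 have exons that overlap a gene on the opposite strand, and whether the counting used strand is not stated.

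All 20 mitosis genes (median 5.67) and all 20 replication genes (median 3.52) were higher in IL-15C naive cells. Mki67 stood at 432 against 8.22 CPM, Top2a at 665 against 13.4 CPM, Ccne2 had a ratio of 6.18 and Rrm2 of 5.97. Together the 40 cell-cycle genes took 0.555% of the reads in IL-15C naive cells and 0.0744% in untreated ones. Interferon-induced genes were higher in 14 of 24 cases (median 1.31), among them Ifi44 (2.49), Oasl2 (2.39), Ifit3 (2.03) and Rsad2 (2.01). Virtual memory markers were higher in 9 of 15 (median 1.48), including Tbx21 (2.35), Cxcr3 (1.62), Eomes (1.44) and Klrk1 (2.25, at 1.10 CPM only 2.11% of its level in IL-15C virtual memory cells). Metabolic lists stood above the random range too: oxidative phosphorylation had a median of 0.67 with 0 of 21 genes beyond 2-fold, such as Cox5b (0.88) and Atp5b (0.42), and glycolysis a median of 0.47 with 2 of 17 higher, Tpi1 (1.21) and Gapdh (1.04).

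Naive and quiescence genes had a median of −0.31 with 2 of 18 lower, Ccr9 and Sox4 (−1.36), and immediate early genes a median of −0.35 with Fos lower (−1.43, 40.0 against 108 CPM). Both lay below the random range, as did the Y-linked genes (−0.59, 0 of 4 beyond 2-fold). Other lists lay within it although some members differed. Cytotoxic genes had 3 of 13 higher (median 0.36), Gzmb (4.62), Gzma (3.59) and Gzmm (1.47). Gzmb was at 37.9 CPM here against 495 CPM in IL-15C virtual memory cells, and Gzmm at 2.425% of its level there. NK receptors had 2 of 5 higher (0.30; Klrc1 3.53, at 1.24% of its IL-15C virtual memory level), and chemokine and trafficking genes 4 higher and 2 lower of 14 (0.23; Ccr2 3.97, at 1.18%, Cxcr6 −1.07). STAT5 targets had 2 of 17 higher (0.19; Socs2 2.93, Il2ra 1.40), apoptosis regulators 1 of 14 (0.14; Bcl2 −0.34), inhibitory receptors 1 of 13 (−0.07; Lag3 1.66), amino acid uptake 1 of 9 (−0.20; Slc43a1 1.90), and integrins 1 higher, Fut7 (1.73), and 1 lower, Itgae (−1.25), of 13 (0.06). Transcription factors had 2 higher, Tbx21 and Eomes, and Rora lower (−0.04, 12 genes), fatty acid oxidation 0 of 17 on either side (0.31), T cell receptor signalling 0 of 15 (−0.01), and the sort gate genes only Itga4 lower (−1.08; median 0.28).

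Markers of other cells went different ways in this comparison. Of 4 B cell genes compared only Cd22 was higher (3.37, counting interval 2.46 to 6.43; median of the list 0.14). Medians were −0.04 for 2 macrophage genes, −0.34 for 5 CD4 genes with Il2ra higher, −0.34 for Itga2b, and −1.09 for 3 dendritic genes, of which Ccr9 was lower, the last of these below the random range. For 3 NK and gamma-delta genes the median was 2.43, above it, with Tcrg-C2 at 3.19 and Tcrg-C1 at 2.43. The share of differing genes that were higher, 71.4%, was 50.1% with the deposited TPM and 82.3% after removal of the trend with transcript length, and this last setting also brought the dendritic median to 0.191 and the Y-linked median into the random range. With the 5 CPM filter the dendritic and the NK or gamma-delta medians lay within the range, the former also without genes held by another list, the NK receptor and CD4 medians were −0.39 and −0.97, and after removal of the length trend the transcription factor median (−0.29) lay below it.

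The study's title concerns virtual memory cells responding to IL-15C, which the comparison of the treated and untreated virtual memory libraries addresses. Gzmb showed the largest ratio among the genes ranked, with 495 CPM against 12.1 CPM (log2 5.35, 95% counting interval 5.23 to 5.48), and Gzma, Klrc1 and Ccr2 were also higher (4.21, 2.75 and 2.22). Ly6a was at 129 against 25.6 CPM (log2 2.34), while Ly6c2 had a ratio of 0.89 from 827 to 1536 CPM. Cd44 (0.06), Klrk1 (0.34) and Ifng (−0.02) stood close to their untreated levels. Some genes of the naive state, such as Il7r (−1.61), and most of those of immediate early transcription, such as Jun (−2.82), were lower, as was Itga4 (−2.79).

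Of 12370 genes compared in virtual memory cells, 1064 were higher and 1092 lower with IL-15C. After Gzmb came, among the genes ranked, Rsc1a1 (5.34), Neurl1b (5.17), Kif2c (4.65), Melk (4.55), Ccnb2, cyclin B2 (4.55), Mxd3 (4.53), Pimreg (4.51), Birc5, survivin (4.50), and Troap (4.50). Rsc1a1 shares exon sequence with Ddi2 on the same strand, so its reads are uncertain. At the lower end of the genes ranked, of at least 10 CPM in the higher library, were Ccr9 (−4.49), Trat1, an adaptor of the T cell receptor (−4.12), Mtss1 (−3.87), Scd1 (−3.79), Cd79a (−3.76), Itgae (−3.70), Rarg (−3.64), the imprinted noncoding gene Peg13 (−3.50), Slfn5 (−3.46) and Cers6 (−3.44).

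Again all 20 mitosis genes (median 4.14) and all 20 replication genes (median 2.96) were higher, with Mki67 at 1566 against 117 CPM and Plk1 at a ratio of 4.38. The 40 cell-cycle genes took 1.31% of the reads, against 0.161% in untreated virtual memory cells. Glycolysis genes were higher in 8 of 17 cases (median 0.89), including Gapdh (1.60, 1238 against 408 CPM), Tpi1 (1.55), Pgam1 (1.32) and Ldha (1.24). Oxidative phosphorylation genes were higher in 8 of 21 (median 0.91), with Cox7a2 at 1.48 and Cox5b at 1.33. Fatty acid oxidation genes had 1 of 17 higher, Etfb (1.13), and a median of 0.43, and STAT5 targets 3 of 17 higher, Il2ra (3.35, 46.7 against 4.55 CPM), Socs2 (2.46) and Cish (2.37), with Ccnd2 lower at −1.56 (median 0.47). These 4 metabolic and signalling medians lay above the random range.

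Cytotoxic genes had 6 of 15 higher, Gzmb, Gzma, Serpinb6b (1.89), Serpinb9 (1.78), Gzmm (1.76) and Fasl (1.66), with a list median of 0.21 inside the range. NK receptors had 3 of 10 higher (median 0.63; Klrc1 2.75, Klrc3 1.51, Klrb1c 1.32), integrins 3 higher, including Fut7 (1.98) and Itgam (1.53), and Itgae lower of 14 (0.28), and virtual memory markers 2 higher, Il12rb2 (2.80) and Ly6a, and 1 lower, Xcl1 (−1.16), of 15 (0.34). Chemokine and trafficking genes had 2 higher, such as Ccr2, and Ccr9 and Xcl1 lower of 16 (−0.22). Transcription factors had Bhlhe40 higher (2.37) and 4 of 16 lower, such as Rora (−2.71) and Ikzf2 (−2.21), with a median of 0.04. Interferon-induced genes had 1 of 24 higher, Ifi27l2a (1.18), and a median of 0.03. Apoptosis regulators had 3 higher, such as Fasl and Bak1 (1.30), and Bbc3 lower (−1.24) of 15 (−0.44), amino acid uptake had Slc7a5 higher (1.25) of 9 (−0.04), T cell receptor signalling 0 of 15 on either side (0.02) and the sort gate genes Itga4 lower of 4 (−0.04).

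Below the random range lay immediate early genes, lower in 13 of 16 cases (median −1.36; Jun −2.82, Fos −2.54, Junb −2.14), naive and quiescence genes, lower in 7 of 18 (−0.66; Sox4 −4.23, Igfbp4 −2.48, Bach2 −1.22), and inhibitory receptors, lower in 6 of 13 with Entpd1 (2.24) higher (−1.11; Cd200 −2.50, Ctla4 −2.26, Lag3 −2.14). The Y-linked genes were lower in 2 of 4, Ddx3y (−1.82) and Uty (−1.27), with a median of −1.07. Markers of other cells were mostly lower beside these: B cell genes in 4 of 6 with Cd22 higher at 1.28 (median −1.69; Cd79a −3.76, Ighd −2.23), dendritic genes in 6 of 7 with Itgax higher at 1.37 (−2.40; Cd74 −2.70, H2-Aa −2.40), macrophage genes in 3 of 5 with Cd68 higher at 1.70 (−2.09; Csf1r −4.28) and CD4 genes in 4 of 6 with Il2ra higher (−1.85; Foxp3 −2.52). Erythroid and platelet genes were lower in 4 of 5 (−1.72; Hbb-bs −2.67), within the random range, and NK and gamma-delta genes had Klrb1c higher of 6 (0.08). Scaling by library totals in place of TMM moved the median log2 ratio of all genes in this comparison by −0.11. The inhibitory median lay within the range under the 5 CPM filter (−0.08) and without shared genes (−0.65), as did the macrophage median under the former (−0.20) and, with little change in size, the CD4 median under the latter (−1.498), while the STAT5 and fatty acid medians lay within it after removal of the length trend, which placed the virtual memory marker (0.44), apoptosis (−0.56) and erythroid (−2.12) medians outside it, as omission of shared genes did for virtual memory markers (0.89) and for NK receptors, then above it.

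**Figure D3:**
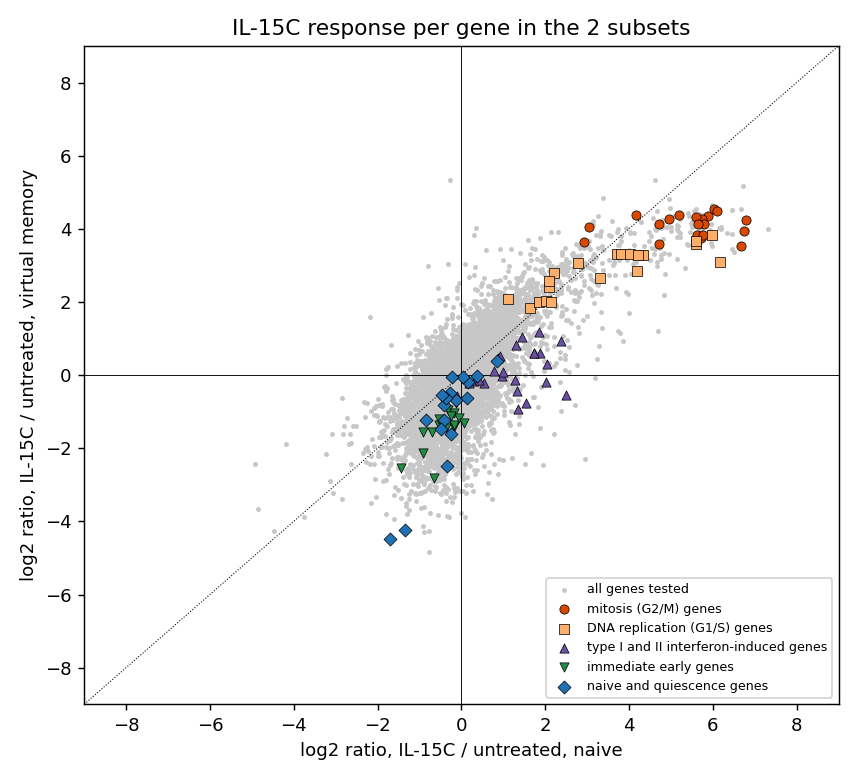
Log2 ratio of IL-15C over untreated in naive cells (horizontal) against virtual memory cells (vertical), with 1 point per gene for 12617 genes and 5 gene lists coloured. Across genes Pearson's r was 0.745; mitosis genes lie high on both axes and interferon-induced genes high on the horizontal axis only, with medians of 1.31 and 0.03.

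The design also asks whether the cytokine complex acted alike in both subsets, and the 2 responses share no library. Across 12617 genes the IL-15C log2 ratios of naive and virtual memory cells had a Pearson's r of 0.745 and a Spearman's rho of 0.692, across genes, which are not independent replicates. Both responses also went with transcript length (Spearman's rho −0.486 in naive and −0.324 in virtual memory cells). Neither the correlation nor the overlaps below were computed without that shared trend. Of 11927 genes compared in both, 495 were higher in both, where independent lists of 590 and 965 genes would share 47.7, and 119 were lower in both (220 and 1018 genes, 18.8 for independent lists). Mitosis genes such as Bub1 and Birc5, replication genes such as Mcm5 (2.21 and 2.79), Gzmb and Ly6a were among those higher in both. Opposite directions were found for Lag3 and Med12l only, where independent lists would give 68.2 such genes. The contrast of virtual memory with naive cells was shared in the same way: of 11848 genes compared in untreated and in IL-15C mice, 389 were higher in both (32.7 for independent lists), 106 lower in both (7.6), and only Neb and Gm20716 went opposite ways (39.8).

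By a 4-fold difference between the responses, 35 of 12617 genes had a higher IL-15C ratio in virtual memory than in naive cells and 236 a lower one, with no test of this difference possible. Highest among the genes ranked, which reach 10 CPM in the highest library, were Rsc1a1 (log2 difference 5.61), Neb (3.36), Tspoap1 (2.51), L1cam (IL-15C ratios of −1.68 in naive and 0.82 in virtual memory cells) and Dpm1 (2.43). Rsc1a1, Dpm1 and L1cam share exon sequence with a neighbouring gene on the same strand. Lowest among the genes ranked were Cd79a (−3.76), Cd74 (−3.57), Mtss1 (−3.52), Plek (−3.48) and Rgs1, a regulator of G protein signalling (−3.35). Rgs1 was higher with IL-15C in naive cells (2.37) and had a ratio of −0.97 in virtual memory cells. Cd79a had 9 and 8 reads in untreated and IL-15C naive cells, and its difference came from the virtual memory libraries (706 and 48 reads). Plek was at 13.8 CPM in IL-15C naive cells, 3.32% of its level in IL-15C virtual memory cells. Carry-over of virtual memory cells into the naive library stays open for a share of this size. Interferon-induced genes had a median difference of −0.95, with 4 of 24 beyond 4-fold, including Ifi44 (−3.02) and Ifit1 (−2.31). A lower IL-15C ratio is not a lower level: mitosis genes were higher in virtual memory than naive cells of untreated (median 3.27) and IL-15C mice (1.88). In the difference between responses, mitosis genes had a median of −1.49 (3 of 20 beyond 4-fold), virtual memory markers of −1.01 (0 of 15), immediate early genes of −0.99 (1 of 16, Jun at −2.18) and naive and quiescence genes of −0.43 (3 of 18), all below the random range. Also below it were the medians of the chemokine (−1.27; Cx3cr1 and Ccr9 beyond 4-fold), transcription factor (−0.95), sort gate (−0.64), replication (−0.46; Cdc6, Rrm2 and Ccne2) and Y-linked genes (−0.85), and those of the dendritic (−2.15), macrophage (−2.01), B cell (−1.72), erythroid (−1.69) and CD4 lists (−1.57). Glycolysis (0.41) and oxidative phosphorylation (0.31) lay above it, and the other 10 lists within it, among them the STAT5 targets (−0.29), of which Cish was beyond 4-fold with a higher ratio in virtual memory cells. The number of genes beyond 4-fold was 138 with a 5 CPM filter, 171 with a prior count of 10, 35 with FPKM and 56 with TPM in place of 271.

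**Figure D4:**
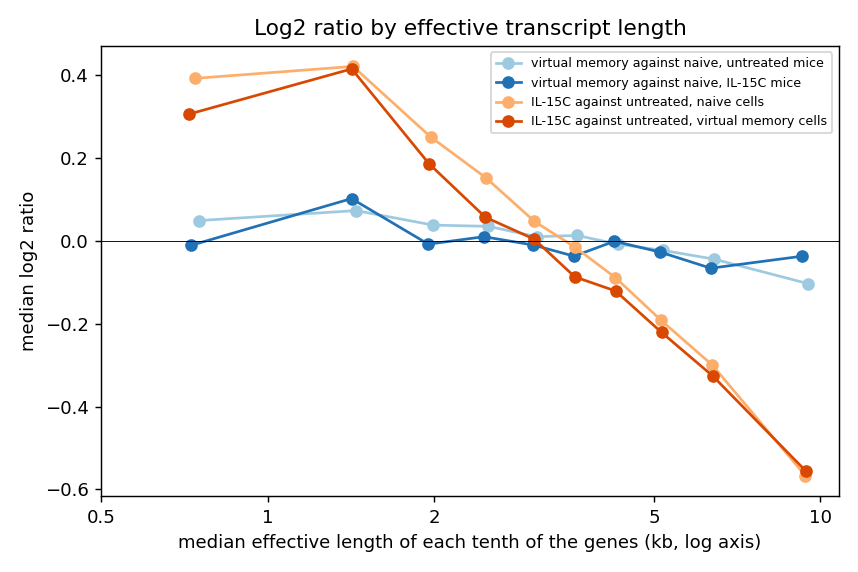
Median log2 ratio of 10 equal groups of genes ordered by effective transcript length, in kilobases, for the 4 comparisons. With IL-15C the group of shortest genes had medians of 0.39 in naive and 0.31 in virtual memory cells, and the group of longest genes −0.57 and −0.56.

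The IL-15C ratios went with transcript length. Spearman's rho across genes between the log2 ratio and the effective length was −0.486 in naive and −0.324 in virtual memory cells, against −0.127 and −0.039 for virtual memory over naive cells in untreated and IL-15C mice. Among the genes named above, Ahnak (−1.89) and Pkd1 (−1.67) in naive cells encode long transcripts, and oxidative phosphorylation genes such as Cox5b (0.88) and Ndufa4 (0.76) short ones. After removal of the length trend, the oxidative phosphorylation medians for IL-15C stayed above the random range in both subsets.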

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

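The carry-over test was chosen after the result it measures had been seen, and removal of the length trend was added as an alternative after the trend had been seen. The differences between groups listed next were not tested, since each group had 1 library.

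Some results went opposite ways in groups under the same contrast. The median log2 ratio of virtual memory over naive cells of the immediate early genes was 0.24 in untreated and −0.89 in IL-15C mice, a difference of −1.13. Neb had ratios of −1.91 and 1.45 in the same contrasts, a difference of 3.36. Gm20716, which shares exons with Dpm1, was at 29.0 and 71.8 CPM in untreated naive and virtual memory cells and at 57.6 and 14.4 CPM in IL-15C ones, a difference of log2 ratios of −3.31. Lag3, with 0.452 CPM in untreated naive, 7.77 in untreated virtual memory, 1.52 in IL-15C naive and 1.73 in IL-15C virtual memory cells, had IL-15C ratios of 1.66 in naive and −2.14 in virtual memory cells, a difference of −3.80. Med12l had IL-15C ratios of −2.18 and 1.59, a difference of 3.78.

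Mitosis genes were higher in IL-15C naive than in untreated naive cells (median log2 5.67, 20 of 20 genes). Virtual memory cells carried over into the naive gate would bring their other transcripts too, yet 18 genes restricted to virtual memory cells in untreated mice (at least 32-fold higher there, outside the cell-cycle lists, and at least 20 CPM in the IL-15C virtual memory library) reached a median of 1.86% of their IL-15C virtual memory level in the IL-15C naive library (range 0.383% to 6.63%), against 27.2% for the mitosis genes, whose lowest value was 11.9%. The trend with transcript length was too small to be the source: medians of 10 equal length groups ran from 0.42 to −0.57 in this comparison. Removing the trend left the mitosis median at 5.73 and its lower quartile at 5.11. The small trend fixed that outcome in advance, so it adds no further evidence. Entry of CD44-negative cells into the cell cycle under IL-15C is a candidate explanation that stays open, found and tested on the same libraries. Dividing cells that had not yet gained, or had lost, surface CD44 and the restricted transcripts were not separated from it here. Carry-over stays open for the higher values of the restricted genes themselves, such as Plek (3.32%), Klrk1 (2.11%), Gzmm (2.425%) and Ccr2 (1.18%). Gzmb and Gzma were outside the restricted set, and carry-over was not tested for them.

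With IL-15C, long transcripts were lower and short ones higher in virtual memory cells (Spearman's rho across genes −0.324). Removal of the trend kept 1603 of the 2156 genes that differed at least 2-fold in virtual memory cells, 74.4%. The trend therefore does not account for most of the genes in that comparison. A trend with GC content is argued against by a rho of −0.309 after its removal, over the 85.8% of genes with a GC value. Fragmentation or length selection in this library alone is argued against by the rho of −0.486 in the IL-15C naive library. Whether both IL-15C libraries were prepared apart from the untreated ones is not stated, so preparation and treatment both stay open as sources. The share of 74.4% does not extend to naive cells, where the trend was stronger and the number kept is not given here. Of the 242 genes lower with IL-15C in naive cells, 124 lay in the longest of 10 equal length groups and 6 in the shortest. For the 603 higher genes these numbers were 36 and 66.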

How the results depend on the processing

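The length trend alternatives were chosen after seeing the data. No paired analysis was possible for the 4 comparisons because each has 1 library per side and the labels give no replicate numbers. A fit of treatment over both subsets with subset as a block is possible with 4 libraries, but asks for a shared effect and was not run. The DESeq2 test, replicate block, fits of 2 groups, leave-one-out fits, camera and fry were planned for groups with replicates only and were not run, and settings for a table without counts did not apply. Genes named in the rankings of the 4 comparisons or in the fixed set were checked with DESeq2 size factors, library totals and prior counts of 0.5 and 10. All kept their side of the limit (568 comparisons with the main value). Direction was compared only for genes counted as higher or lower, and these kept it. The ranking by the difference between responses, and further list members, were not checked in this way. Counts of differing genes stayed within 1.5 times except as follows. A 4-fold limit gave 304 genes for virtual memory over naive cells in untreated mice, 348 in IL-15C mice, 303 for IL-15C in naive and 550 in virtual memory cells, by construction. A filter at 5 CPM gave 467 in untreated mice and 138 for different responses, having fewer genes to compare. For genes changed, virtual memory against naive, untreated mice, FPKM gave 415, and it gave 35 for different responses, TPM gave 56 for the latter and a prior count of 10 gave 171; the cause was not tested. The correlation of the IL-15C responses ranged from 0.745 to 0.818. Of 427 list medians under alternatives, 398 kept their place relative to the random range, 19 moved into it, 9 moved out of it and 1 outside it reversed. The reversed one, the dendritic median for IL-15C in naive cells, on 3 genes, was −1.09 and became 0.191 after removal of the length trend. The cause was not tested. Direction was not compared for medians within the range. Some of these changed sign, such as amino acid uptake for IL-15C in virtual memory cells (−0.037, and 0.008 with DESeq2 size factors). Removing that trend kept 1603 of 2156 differing genes for IL-15C in virtual memory cells.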

Other observations

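The test of a shift toward the virtual memory profile was chosen after the result it measures had been seen. Classes of transcripts other than protein-coding genes also differed with IL-15C in virtual memory cells. Of 44 small nucleolar RNA genes compared 25 were lower and 0 higher (median log2 −1.70), and 20 of 41 were lower in virtual memory than naive cells of IL-15C mice, whereas 0 of 51 differed with IL-15C in naive cells (median −0.17). Of 635 long noncoding RNA genes 140 were lower and 26 higher (median −0.73), and of 759 pseudogenes 133 were higher and 9 lower (median 0.62). Both classes went the same way with IL-15C in naive cells, where 66 of 637 long noncoding RNA genes were lower and 17 higher (median −0.44), and 36 of 726 pseudogenes were higher and 3 lower (median 0.41). These classes include short and unpolyadenylated transcripts and copies of expressed genes, so reads shared with parent genes are uncertain.

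The Y-linked gene Ddx3y was at 128 and 122 CPM in untreated naive and virtual memory cells, 70.0 CPM in IL-15C naive and 34.6 CPM in IL-15C virtual memory cells, and Uty at 34.7, 35.2, 24.3 and 14.5 CPM. Their X-linked counterparts, chosen after their values were seen, had IL-15C ratios in virtual memory cells of −0.52 (Ddx3x) and −0.78 (Kdm6a), beside −1.82 and −1.27 for the Y-linked genes. For Eif2s3y the ratio was −0.83 and for Eif2s3x 0.27. Xist was not analysed here, so the sex of the mice had no second measure.

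The authors' deposited table gives 4044 genes with an adjusted p under 0.05 for IL-15C against untreated naive cells, of which 960 were at least 2-fold higher and 636 lower, and 6719 for virtual memory cells (1512 higher and 2004 lower). In the authors' deposited table the subsets differed in 1617 genes in untreated mice and in 5129 in IL-15C mice, and both IL-15C libraries against both untreated ones in 502 (440 higher and 62 lower). The test behind these values is not stated, and all but the last of these comparisons have 1 library per side.

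A hypothesis was that IL-15C moves naive cells toward the virtual memory profile. Outside the cell-cycle lists, 617 genes higher in virtual memory than naive cells of IL-15C mice had a median IL-15C log2 ratio of 0.82 in naive cells, above matched random lists, with 229 higher and 15 lower. This could reflect a shared response to the cytokine in both subsets, which these sets cannot separate. The 274 genes that were not also higher with IL-15C in virtual memory cells had a median of −0.15, below random lists. Of these, 144 that were also higher in virtual memory cells of untreated mice had a median of 0.43, above them. All of these sets were chosen for lower values in the IL-15C naive library, which by selection lowers the ratio. The 144 genes were also chosen for lower values in the untreated naive library, which raises it. The sets point different ways, so the hypothesis was left undecided.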
